A study of Drosophila melanogaster with 12 samples.

How the data were processed

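Reproductive tracts of virgin Drosophila melanogaster males were measured by stranded total RNA sequencing. Per the labels, 6 populations derived from a single base population had evolved for 168 generations under 2 mating regimes. In the 3 monogamous populations each male was housed with 1 virgin female, and in the 3 polygamous populations 5 males were housed with 5 females. Males of each population were aged for 48 or 96 h, and each of the 12 libraries pooled 30 tracts, which held the accessory glands, the testes and the ejaculatory duct. Each group of regime and age therefore held 3 libraries, numbered here by population. A population is a separate evolving line, so the spread within a regime is the spread between lines, and 1 pool stood for each line at each age.

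The deposited values were raw read counts per gene, 1 table per library. Per the submitters' processing notes, the authors used Trimmomatic 0.33, TopHat2 2.1.0 and HTSeq 0.6.1 with genome build BDGP6. The annotation release, the strand setting and the counting mode were not given in the sources used here, so the count of a gene that overlaps another, on either strand, is uncertain. Overlaps of genes named by the rule are given with the gene or here. On the same strand these were lncRNA:CR45883 with CG32085, glob3 with CG1208, CG42764 with atk, and Ddx56, sta, RpL5, ND-MLRQ and ATPsynC with small RNAs. On the other strand they were lectin-46Ca with CG1648, bam with CG11854, Acp36DE with Fas3, lncRNA:CR45883 also with lncRNA:CR45880, Sfp24Bb with Drgx, Cyp4p2 with hig, FIG4 with ine, CG31910 with meng, CG3502 with CG9863, Cyp9c1 with CG13594 and asRNA:CR43787, epsilonCOP with Phf5a, RpL24-like with Dtd, and Mst87F, Abd-B and kl-3 with non-coding genes. Each table listed 17559 genes and 5 summary lines. The summary lines held 15.1% to 17.2% of all reads counted per library and stayed out of library sizes and tests. Gene symbols, positions and gene types came from the BDGP6.54 annotation of Ensembl, in which 17253 of the 17559 identifiers had a symbol. The 306 others entered the tests and are not named.

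Gene counts summed to 31367000 to 40581000 per library, so 3 counts were worth 0.0739 to 0.0956 CPM (counts scaled to library size by edgeR). No files of a group held identical values, and the chi-square per degree of freedom between replicates lay from 12.1 to 199.9, far above sampling noise.

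Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3, robust estimation) after TMM normalisation and filterByExpr, with 1 coefficient per group and 1 dispersion fit over all 12 libraries. Of the deposited genes, 13156 passed the filter, 214 of them without a symbol. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were 96 against 48 h within each regime and averaged over both, polygamy against monogamy at each age, and the difference of the 2 age changes. A further comparison of the regimes summed the libraries of each population and set 3 sums against 3 (13512 genes tested), since a population measured at both ages is 1 replicate of its regime. Fold changes are edgeR estimates, errors of log2 changes are standard errors (SE) from the fit, and CPM are given as mean and SD.

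The 2 libraries of a population deviated together from their group means, with correlations over genes of 0.473, 0.459 and 0.570 for monogamous populations 1 to 3 and 0.507, 0.390 and 0.518 for polygamous populations 1 to 3. Among the 96 h libraries, each 48 h library correlated best with that of its own population. The population was therefore a true block for the age comparisons, and blocked values are printed beside counts over all genes and beside calls of lists and named genes that the block altered. Counts of list members with the block are printed for part of the lists.

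Gene lists were written from general knowledge before the data were examined, 30 in all, and none was chosen on these samples. They covered named and candidate seminal fluid proteins, the sex peptide network, secondary cell markers, ejaculatory duct and bulb, early germline, the spermatocyte programme, spermatid and late spermatogenesis, Y-linked genes, somatic testis cells, muscle, fat body, haemocytes and basement membrane, gut enzymes, Malpighian tubule, neurons, ribosomal proteins, ER translocation and folding, COPI, COPII and Golgi traffic, the unfolded protein response, oxidative phosphorylation, the mitochondrial genome, the cytosolic proteasome, cell cycle and DNA replication, antimicrobial peptides and immune effectors, heat shock, insulin and TOR signalling, ecdysone and juvenile hormone, the circadian clock, and metabolic detoxification. All 9 members of the sex peptide network, 3 secondary cell markers and 3 duct and bulb genes were also on the list of named seminal fluid proteins, and the candidate list shared 2 genes with the secondary cell markers. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the 30 lists. Counts of members were taken over all genes tested and adjusted over the list alone. The percent of gene counts taken by a list was compared with exact two-sided permutation tests, whose smallest p is 0.1 for 3 libraries against 3 and 0.00216 for 6 against 6 (scipy 1.17.1).

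The genes named were fixed by a rule written before the data were examined. For each comparison it took up to 10 genes per direction with the largest change among called genes with a mean of at least 5 CPM and no overlap between the groups, up to 4 called members per list with the smallest adjusted p, and a panel of SP, Acp26Aa, Acp36DE, Dup99B, lectin-46Ca, Abd-B, betaTub85D, Mst87F and bam whatever their p. Where fewer than 10 genes passed, the 5 with the smallest p in each direction with a mean of at least 5 CPM were named as not passing. The text gives part of the first and second sets in rank order. Genes named outside the rule are marked as chosen after their values were seen.

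Alternatives in scaling were DESeq2 size factors, size factors from the spermatocyte and spermatid lists, and TMM without seminal fluid genes. Alternatives in filtering were no filter and a filter at a mean of 5 CPM. Those in testing were DESeq2 1.42.0 and limma-voom as tests, non-robust estimation, only the 6 libraries compared and the replicate block. Each library was also left out in turn, and for population sums each population. Further fits were added after the data were seen: without both libraries of monogamous population 1, the same with the population as block, without the 96 h libraries of monogamous populations 1 and 3, and the older quasi-likelihood method of edgeR. The tests were run first on simulated counts with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. The simulated libraries were independent, without the correlation within populations given above and without a library that stands apart from the rest. Recovery of real changes could therefore differ, and for population sums could be lower. At a simulated 2-fold change, edgeR recovered 65.7% of changed genes for age in monogamous males, 68.7% in polygamous males, 79.1% for the average of both, 73.1% for the regimes at either age, 50.7% for the difference of age changes and 71.6% for population sums. On the same kind of data 45 of 191 genes called by DESeq2 for the regimes at 48 h were false, against 13 of 153 by edgeR, so DESeq2 counts are given only as an alternative.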

Results

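Whole-transcriptome counts were collected from pooled male reproductive tracts of 6 populations of Drosophila melanogaster, 3 evolved under monogamy and 3 under polygamy, at 48 and 96 h of age. The accessory gland makes most of the seminal fluid, its main cells secreting the bulk of the proteins and its rarer secondary cells a distinct subset, and the study followed gland gene expression as males matured under a history of weak or strong sexual selection. Each of the 4 groups held 3 libraries of 31367000 to 40581000 gene counts, and 14786 to 14968 genes had at least 1 count in a library. The 10 most abundant genes took 6.65% to 8.67% of the counts.

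The 48 h library of monogamous population 1 stood apart from the other 11. It lay at -68.2 on the first principal component, which held 26.8% of the variance, against -26.4 for the 96 h library of the same population and -6.01 to 19.9 for the rest. Named seminal fluid proteins took 3.07% of its counts, against 6.09% to 7.73% in the other 5 libraries at 48 h, and secondary cell markers took 0.0313% against 0.173% to 0.249%. Among panel genes, lectin-46Ca stood at 36.7 CPM in this library and at 260 to 424 CPM in the others, Acp36DE at 2772 CPM against 11035 to 14668, and Dup99B at 2374 CPM against 1174 to 1487. For counts of called genes and for called lists that moved by over 1.5 times without population 1, an alternative added after the data were seen, that value is also given. Numbers of genes with an unadjusted p under 0.05 are given only with all libraries in.

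**Figure D1:**
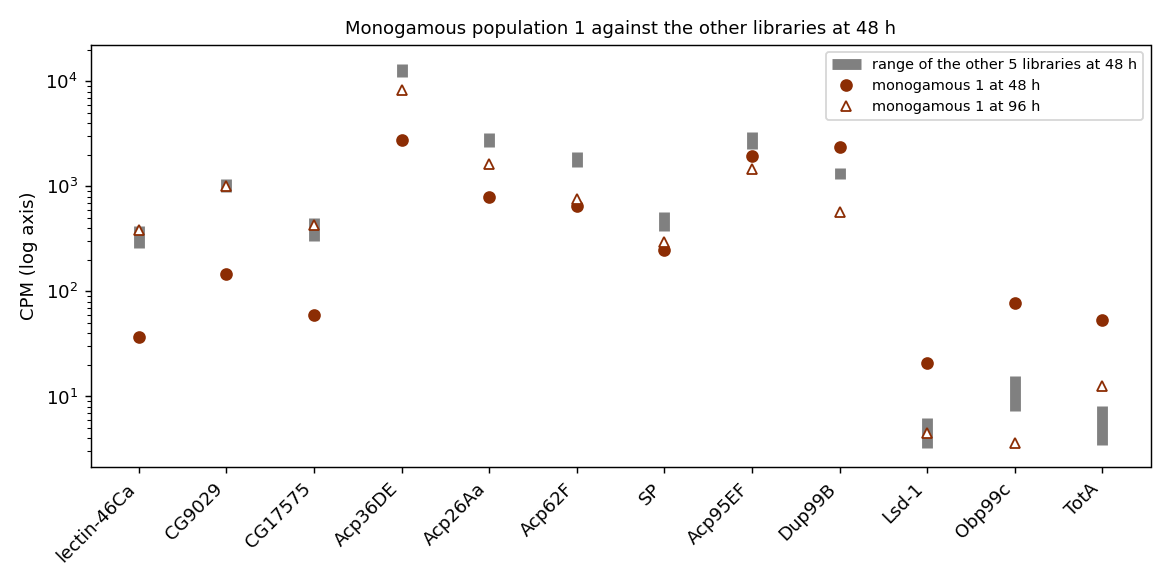
CPM (log axis) of 12 genes, chosen after their values were seen, in monogamous population 1 at 48 h (filled circles) and 96 h (open triangles), with bars for the range of the other 5 libraries at 48 h. lectin-46Ca stood at 36.7 CPM at 48 h against 260 to 424 CPM in the other libraries, while TotA stood at 53.1 CPM against 3.45 to 8.08 CPM.

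Between 48 and 96 h of age, several genes of small secreted proteins fell, averaged over regimes. Sfp79B (FBgn0259973, chromosome 3L, 22080322 to 22080554), a seminal fluid protein gene, fell 6.99-fold (log2 change -2.81 ± 0.26, SE, 6 libraries against 6). The male-specific gene msopa (FBgn0004414, 3L, 22082720 to 22083367) fell 6.83-fold (-2.77 ± 0.24), from 1117 ± 89.8 to 169 ± 59.5 CPM in polygamous males (SD, n = 3). Obp56e, an odorant-binding protein gene on the seminal fluid list, fell 4.76-fold (-2.25 ± 0.26), Sfp36F 2.07-fold (-1.05 ± 0.14) and Sfp93F 1.92-fold (-0.94 ± 0.12). Among called genes with a mean of at least 5 CPM and no overlap between the ages, the largest rises were those of CR43086, annotated as a pseudogene, at 5.45-fold (2.45 ± 0.29), lncRNA:CR44481 at 2.93-fold (1.55 ± 0.20) and CG5397 (FBgn0031327, 2L, 1240036 to 1243018) at 2.71-fold (1.44 ± 0.08). Each of these genes moved the same way in 6 of 6 populations, which the rule made certain by asking for no overlap between the ages.

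Other genes that fell were Obp99b, another odorant-binding protein gene, by 11-fold (-3.46 ± 0.61, and -2.80 ± 0.44 without population 1), CG15021 by 2.76-fold (-1.46 ± 0.20), the globin gene glob1 by 2.22-fold (-1.15 ± 0.09), lncRNA:CR44672 by 1.97-fold (-0.98 ± 0.19) and vkg, which encodes a collagen IV chain of basement membranes, by 1.96-fold (-0.97 ± 0.19). CG3690 rose 2.27-fold (1.18 ± 0.21), CG14022 2.26-fold (1.17 ± 0.16), laza, a lipid phosphate phosphatase gene, 2.24-fold (1.16 ± 0.16) and CG10175 2.104-fold (1.07 ± 0.15). CG6055 rose 1.84-fold (0.88 ± 0.09), CG42521 1.82-fold (0.86 ± 0.13) and CG43788 1.80-fold (0.84 ± 0.10). CG43788 overlaps Pkc53E on the same strand and Obp56e overlaps asRNA:CR44509 on the other strand, so their counts could include reads of the partner. All of these genes had an edgeR Benjamini-Hochberg adjusted p from 1.29e-05 (CG5397) to 0.0372 (vkg).

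Averaged over regimes, 194 of 13156 genes changed with age (edgeR quasi-likelihood test), 109 up and 85 down, and 475 with the population as replicate block. With size factors from testis genes the split was 108 up and 52 down of 160. DESeq2 gave 627 calls. Without population 1 the count was 805, 338 up and 467 down, and 188 of the 194 genes were among them. Leaving out only its 48 h library gave 914, its 96 h library 104, the 96 h library of monogamous population 3 gave 117 and any 1 polygamous library gave 80 to 106.

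Named seminal fluid proteins ranked low as a group. Of 77 measured members 6 fell, 0 rose and 71 did not pass, and adjusted over the list alone 12 fell. The replicate block gave 9 down and 2 up. The median log2 change was -0.15 (camera, adjusted p = 1.07e-07, and adjusted p = 0.570 with an estimated correlation). The ovulation-inducing Acp26Aa (-0.60 ± 0.25, edgeR adjusted p = 0.260), the sperm-storage protein gene Acp36DE (-0.39 ± 0.30, adjusted p = 0.529), the ejaculatory duct peptide gene Dup99B (-0.86 ± 0.22, adjusted p = 0.0845) and the sex peptide gene SP (-0.03 ± 0.16, adjusted p = 0.954) did not pass.

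Without monogamous population 1, 26 of the 77 fell, 0 rose and 51 did not pass, and adjusted over the list alone 42 fell and 1 rose. Adding the replicate block to that fit, 50 fell, 8 rose and 19 did not pass. Acp26Aa then fell 1.70-fold (-0.76 ± 0.07, edgeR adjusted p = 0.000659) and Acp36DE 1.51-fold (-0.59 ± 0.08, adjusted p = 0.00348), while SP gave -0.06 ± 0.13 (adjusted p = 0.871). Among genes chosen after their values were seen, Acp76A, a serpin, fell 2.84-fold (-1.50 ± 0.08), Acp62F, a protease inhibitor gene, 1.96-fold (-0.97 ± 0.07) and Acp63F 1.60-fold (-0.67 ± 0.08). The list's median was -0.27 (adjusted p = 0.201 with an estimated correlation). Its share of counts went from 7.31% ± 0.693 to 5.28% ± 0.485 (SD, n = 5), lower in 5 of 5 populations (exact permutation p = 0.00794, the smallest that 5 libraries against 5 can give, Benjamini-Hochberg adjusted p = 0.0595 over 30 lists). Over all 12 libraries it went from 6.60% ± 1.84 to 5.20% ± 0.469 (n = 6, exact p = 0.0909, adjusted p = 0.210), lower in 5 of 6.

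**Figure D2:**
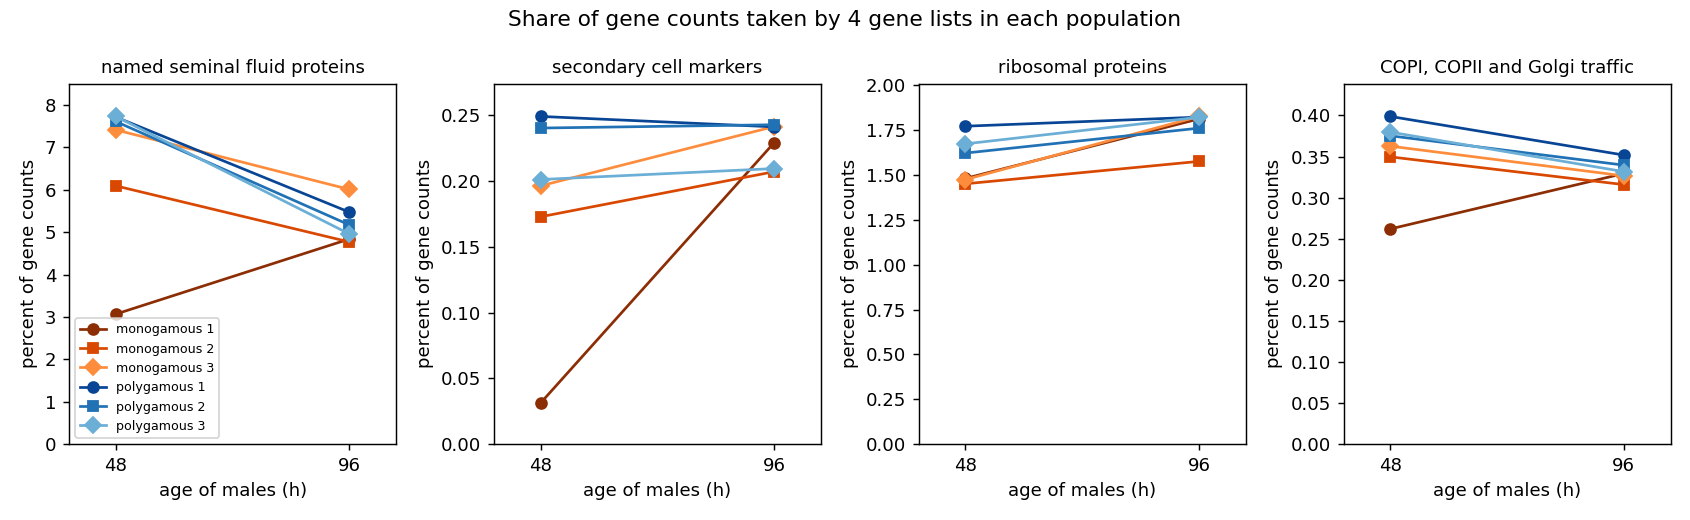
Percent of gene counts taken by 4 gene lists (vertical axis) in each of the 6 populations at 48 and 96 h (horizontal axis); each point is 1 library and lines join the libraries of a population. The share of named seminal fluid proteins was lower at 96 h in 5 of 6 populations, and monogamous population 1 went from 3.07% to 4.84%.

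Lists of the secretion machinery had negative medians too. Of 28 genes of COPI, COPII and Golgi traffic 1 fell, epsilonCOP (1.17-fold, -0.23 ± 0.05), and the list's median was -0.18 (adjusted p = 2.80e-07, and adjusted p = 0.527 with an estimated correlation); adjusted over the list alone 4 fell. Of the traffic list 2 fell with the replicate block. Without population 1, 17 fell and 0 rose (24 fell adjusted over the list alone), among them Sec24CD (1.36-fold, -0.44 ± 0.04), alphaCOP (1.29-fold, -0.37 ± 0.03) and Sec16 (1.22-fold, -0.29 ± 0.03), chosen after their values were seen, with adjusted p = 0.201 with an estimated correlation. Of 27 genes of ER translocation and folding 0 passed over all libraries (edgeR; median -0.10, adjusted p = 0.00499, and adjusted p = 0.590 with an estimated correlation). Without population 1, 11 fell (18 adjusted over the list alone), with a median of -0.18, among them the chaperone genes Hsc70-3 (1.26-fold), Gp93 (1.25-fold) and Grp170 (1.28-fold), chosen after their values were seen, with adjusted p = 0.201 with an estimated correlation. Adding the replicate block to that fit, 21 genes of the folding list fell. The 12 genes of the unfolded protein response had a median of -0.0047 and 0 passed (camera adjusted p = 0.975).

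Of 61 candidate seminal fluid proteins 2 rose, CG18628 (1.36-fold, 0.44 ± 0.07, from 2774 ± 129 to 3796 ± 429 CPM in monogamous males, n = 3) and Bbd (1.55-fold, 0.63 ± 0.12), 4 rose and 1 fell adjusted over the list alone, and the median was -0.0021 (adjusted p = 0.605). The replicate block gave 4 up and 2 down. Without population 1, 5 of them rose and 10 fell (8 and 34 with the block in that fit), and the median was -0.17 (adjusted p = 2.40e-06, and adjusted p = 0.571 with an estimated correlation). The 9 genes of the sex peptide network (median 0.20, adjusted p = 0.227) and the 9 secondary cell markers (median 0.27, adjusted p = 0.204) had 0 members past the threshold, and their medians without population 1 were 0.01 and 0.03. With the block in that fit 3 members rose and 2 fell in each of these lists. The panel genes lectin-46Ca (0.36 ± 0.39) and Abd-B, the Hox gene needed in secondary cells (-0.13 ± 0.13), did not pass. The ejaculatory duct and bulb list took 0.502% ± 0.0563 of counts at 48 h and 0.339% ± 0.0817 at 96 h (n = 6), lower in 6 of 6 populations (exact permutation p = 0.00866, adjusted p = 0.0519), while its median log2 change was -0.01, its mean 0.38, with 0 of 8 members passing (1 up and 1 down with the replicate block), and camera gave adjusted p = 0.649.

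The ribosomal protein list had a positive median over both regimes, with 0.16 in monogamous and 0.01 in polygamous males. Of 87 measured, 4 rose and 0 fell (7 and 0 with the replicate block, 7 and 0 without population 1, and 34 and 0 with both changes): RpL24-like, which acts in large-subunit assembly (1.28-fold, 0.36 ± 0.05), sta (1.23-fold, 0.30 ± 0.05), RpL5 (1.22-fold, 0.29 ± 0.06) and RpS2 (1.17-fold, 0.23 ± 0.05). The list's median was 0.09 (adjusted p = 7.38e-08, and adjusted p = 0.554 with an estimated correlation), 8 rose adjusted over the list alone, and its share went from 1.58% ± 0.130 to 1.77% ± 0.0982, higher in 6 of 6 populations, without passing correction (exact permutation p = 0.0260, adjusted p = 0.111). Of 86 oxidative phosphorylation genes 2 fell, ND-MLRQ (1.26-fold, -0.33 ± 0.06) and ATPsynC (1.21-fold, -0.27 ± 0.05), 17 fell and 1 rose adjusted over the list alone, and the median was -0.13 (adjusted p = 9.17e-13, and adjusted p = 0.527 with an estimated correlation). The 14 mitochondrial genome transcripts (median -0.11, adjusted p = 0.00499, and adjusted p = 0.558 with an estimated correlation) and the 31 proteasome genes (median -0.06, adjusted p = 0.00257, and adjusted p = 0.527 with an estimated correlation) had 0 members past the edgeR threshold. Using the block, 8 oxidative phosphorylation genes fell and 1 rose, and 1 mitochondrial genome transcript fell. Without population 1, 14 oxidative phosphorylation genes fell and 2 rose (31 and 3 with the block in that fit), with a median of -0.06, and the mitochondrial genome was not called (adjusted p = 0.0904, and 0.0279 with the replicate block in that fit). RpL5 did not pass there (adjusted p = 0.0524, and 0.000115 with the block).

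Cell cycle and DNA replication was the only one of the 30 lists that fry called (adjusted p = 0.0460). Its member polo, a mitotic kinase, rose 1.13-fold (0.18 ± 0.04), 25 others did not pass, the median was 0.13 (adjusted p = 0.000372, and adjusted p = 0.527 with an estimated correlation), and its share went from 0.0941% ± 0.00308 to 0.107% ± 0.00543, higher in 6 of 6 populations (exact permutation p = 0.00216, the smallest possible, adjusted p = 0.0325). Heat shock genes went from 0.418% ± 0.0150 to 0.479% ± 0.0189 of counts with the same p values, higher in 6 of 6 populations, while 0 of 14 passed alone, 4 rose adjusted over the list alone, and the list's median was -0.02 (adjusted p = 0.307). With the populations as pairs both share calls were lost, at the smallest p that 6 pairs can give (exact p = 0.03125, adjusted p = 0.0938). Without population 1 the differences were as large and in 5 of 5 populations, from 0.0932% ± 0.00252 to 0.107% ± 0.00605 and from 0.422% ± 0.0142 to 0.481% ± 0.0208. Both then had the smallest p that 5 libraries against 5 can give (exact permutation p = 0.00794, adjusted p = 0.0595). By edgeR 4 cell cycle genes then rose, and 8 rose and 1 fell with the replicate block in that fit. Over all libraries the block called 2 cell cycle and 2 heat shock genes upward.

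Among testis lists, the 40 spermatid genes had a median of -0.11 with 0 passing (adjusted p = 2.80e-07, and adjusted p = 0.554 with an estimated correlation), and the 12 Y-linked genes -0.13 with 0 passing (adjusted p = 0.00874, and adjusted p = 0.527 with an estimated correlation). The spermatocyte programme had a median of 0.11 (adjusted p = 0.0672, and 0.0327 with the replicate block, lost at adjusted p = 0.715 with an estimated correlation), early germline 0.13 (adjusted p = 0.0991) and somatic testis cells 0.06 (adjusted p = 0.562). With population 1 left out, the spermatid median was -0.05 and the Y-linked list was not called (-0.09, adjusted p = 0.0959). The spermatocyte programme was then called (0.12, adjusted p = 0.0191, and adjusted p = 0.559 with an estimated correlation). The panel genes betaTub85D, a testis tubulin (-0.09 ± 0.07), Mst87F, a sperm protein gene (-0.17 ± 0.10), and bam, a germline differentiation gene (0.13 ± 0.11), did not pass. Size factors from testis genes moved the median of all genes from 0.01 to 0.07 in this comparison, to 0.12 for age in monogamous males and to 0.14 for the regimes at 48 h.

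Lists of blood cells, fat body and immune effectors had negative medians, with few members past the threshold. Of 13 haemocyte and basement membrane genes 2 fell, vkg and the collagen-binding SPARC (1.52-fold, -0.60 ± 0.12), and the median was -0.41 (adjusted p = 4.71e-05, and adjusted p = 0.527 with an estimated correlation). Of 16 immune effectors BomBc2, a bomanin, fell 13.2-fold (-3.72 ± 0.70, and -3.07 ± 0.39 without population 1), with a median of -0.30 (adjusted p = 0.000439, and adjusted p = 0.527 with an estimated correlation). BomBc2 overlaps BomS4 on the other strand. The 13 fat body genes (median -0.89, adjusted p = 2.11e-06, and adjusted p = 0.527 with an estimated correlation) and the 22 muscle genes (median -0.10, adjusted p = 0.00702, and adjusted p = 0.527 with an estimated correlation) had 0 members past the threshold. Without population 1, whose 48 h library was high in haemocyte, fat body and immune transcripts, the medians were -0.12 for haemocyte genes (3 fell), -0.18 for immune effectors (3 fell), -0.64 for fat body (0 fell) and -0.16 for muscle (5 fell). Using the block, 4, 5, 4 and 3 genes of these lists fell over all libraries, and 6, 6, 7 and 13 without population 1. Of 120 detoxification genes 3 rose, among them the cytochrome P450 gene Cyp9c1 (2.31-fold, 1.21 ± 0.20) and Ugt36D1 (1.29-fold), and 3 fell. Among those that fell were the glutathione transferase genes GstD5 (1.56-fold, -0.65 ± 0.09) and GstD4 (2.64-fold). GstD4 had a mean of only 0.270 CPM, and 0.0921 CPM in monogamous males at 96 h, near the value of 3 counts. The list's median was -0.12 (camera adjusted p = 0.00702, and adjusted p = 0.527 with an estimated correlation). The replicate block gave 5 up and 8 down. Without population 1, 5 rose and 10 fell (9 and 30 with the block in that fit), and GstD4 did not pass (adjusted p = 0.0550, and 0.0222 with the block). Gut enzymes (median 0.02, adjusted p = 0.605), Malpighian tubule (0.21, 0.227), neurons (-0.09, 0.397), insulin and TOR signalling (0.11, 0.157), ecdysone and juvenile hormone (median 0.03, mean -0.04, 0.649) and circadian clock genes (0.03, 0.389) were not called and had 0 members past the threshold. In the fit without population 1 the ecdysone and juvenile hormone list was called (-0.04, adjusted p = 0.0342), but not with the replicate block added (0.131) or with an estimated correlation (adjusted p = 0.473).

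**Figure D3:**
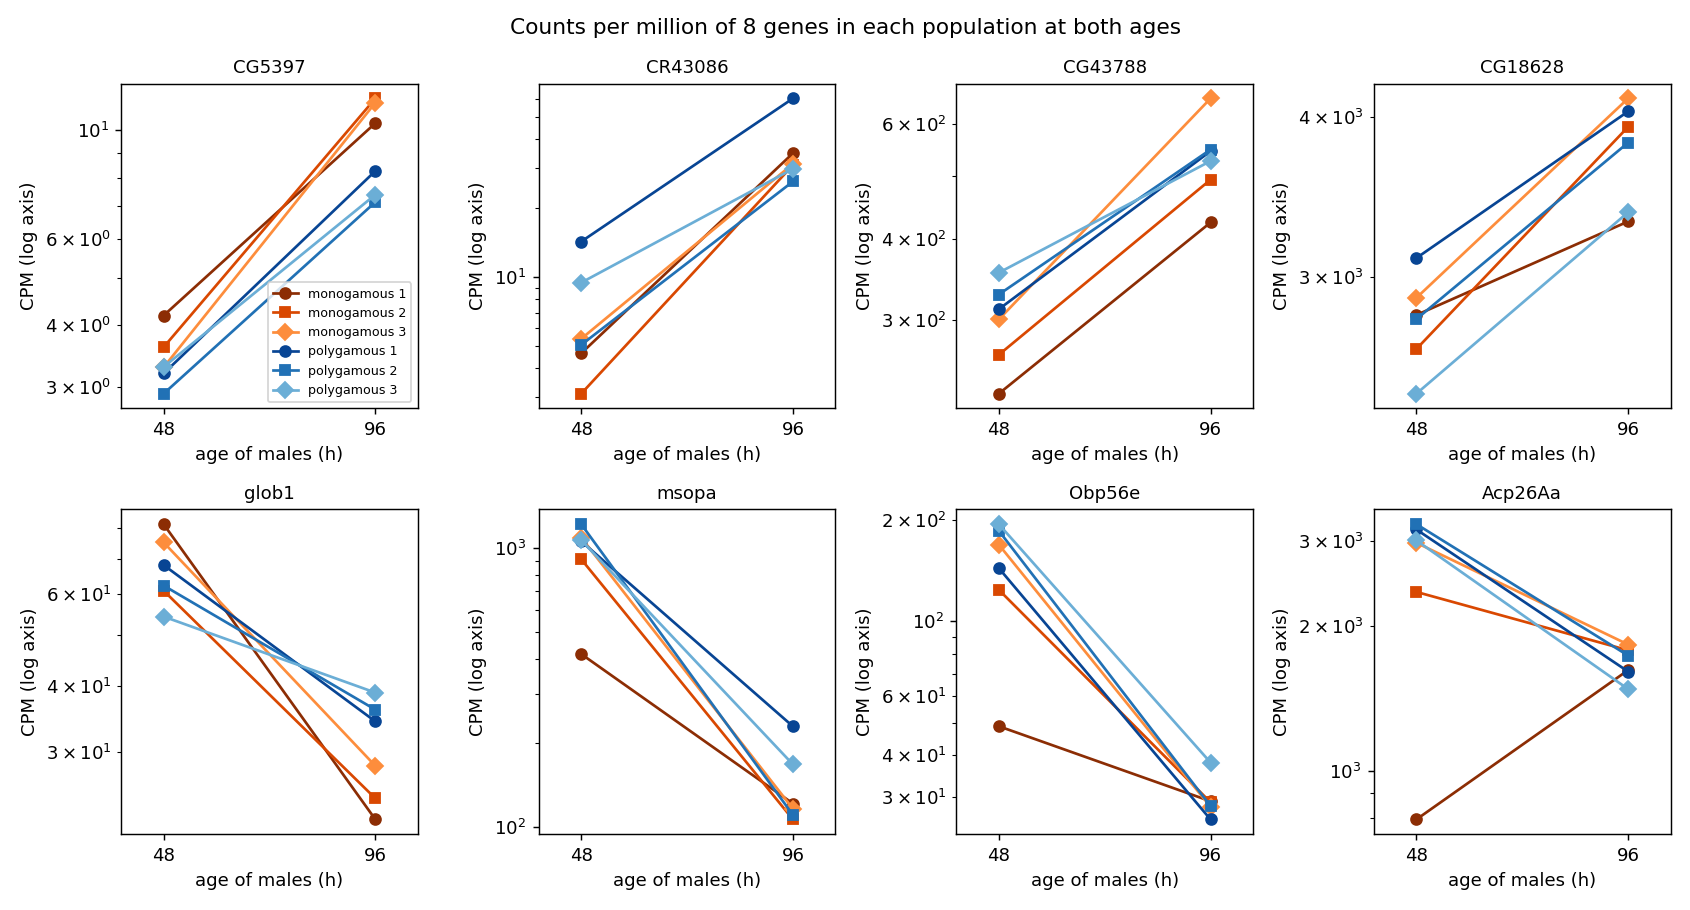
CPM (log axis) of 8 genes in each of the 6 populations at 48 and 96 h (horizontal axis); each point is 1 library and lines join the libraries of a population. The first 7 genes had no overlap between the ages and so moved the same way in 6 of 6 populations, and Acp26Aa was lower at 96 h in 5 of 6.

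In monogamous males alone, CR43086 rose 7.34-fold between the ages (2.88 ± 0.42, 3 libraries against 3), lncRNA:CR44481 3.53-fold, CG5397 3.02-fold (1.59 ± 0.11), laza 2.84-fold, CG14022 2.80-fold and CG10175 2.46-fold. msopa fell 7.06-fold (-2.82 ± 0.35), Sfp79B 7.01-fold (-2.81 ± 0.37), glob1 2.91-fold (-1.54 ± 0.13), from 72.6 ± 10.6 to 24.9 ± 2.99 CPM, and CG9360 2.38-fold (-1.25 ± 0.19). Further called genes were asRNA:CR45149 (2.06-fold up), CG43788 (1.98-fold up), CG14142 (1.97-fold up), Sfp93F (1.98-fold down), CG15210 (1.88-fold down), Erasp (1.72-fold down), GstD5 (1.70-fold down) and CG10553 (1.66-fold down). Obp56e fell 3.97-fold (-1.99 ± 0.36, edgeR adjusted p = 0.0487) and did not pass with the replicate block (adjusted p = 0.0643). asRNA:CR45149 overlaps Arms on the other strand, CG9360 overlaps m and CG15210 overlaps sbr.

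In these males 72 genes changed (edgeR), 52 up and 20 down, and 252 with the replicate block. Size factors from testis genes gave 27 calls (21 up, 6 down), DESeq2 338, limma-voom 45 and a fit of only the 6 libraries compared 3. Without population 1 the count was 91, 34 up and 57 down. Without its 48 h library it was 157, without its 96 h library 6, without the 48 h library of population 2 it was 5, and without the 96 h library of population 3 it was 12. By list, 3 of 77 named seminal fluid proteins fell and 74 did not pass, with 6 up and 5 down adjusted over the list alone and 6 up and 4 down with the replicate block. The list's median was 0.10 over all libraries (adjusted p = 0.925). Without population 1 it was -0.14 and called downward (adjusted p = 3.27e-14, and adjusted p = 0.485 with an estimated correlation). Of 87 ribosomal proteins RpL24-like and sta rose (1.32-fold and 1.34-fold; 7 up and 0 down with the replicate block; 34 up and 1 down adjusted over the list alone; median 0.16, adjusted p = 3.54e-16, and adjusted p = 0.475 with an estimated correlation). The sex peptide network (median 0.49, adjusted p = 0.00166) and the secondary cell markers (0.66, adjusted p = 0.00456) were called upward with 0 members past the threshold, with adjusted p = 0.484 and 0.475 with an estimated correlation. Their medians without population 1 were 0.19 and 0.20 and neither was called (adjusted p = 0.0752 each), while with the replicate block in that fit both were (adjusted p = 0.00145 and 0.000430).

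In polygamous males, msopa fell 6.61-fold (-2.72 ± 0.34, 3 libraries against 3), Sfp79B 6.97-fold (-2.80 ± 0.36) and the odorant-binding protein gene Obp58b 3.55-fold (-1.83 ± 0.25). CG5397 rose 2.43-fold (1.28 ± 0.12), CG6055 1.78-fold (0.83 ± 0.13) and FANCI, a DNA repair gene, 1.47-fold (0.56 ± 0.08). Obp56e fell 5.71-fold (-2.51 ± 0.37, edgeR adjusted p = 0.0451) and Npc2b, of a sterol-binding family, 2.07-fold (-1.05 ± 0.15, adjusted p = 0.0277), and with the replicate block both had adjusted p = 0.0520. Acp26Aa went from 3141 ± 123 to 1607 ± 128 CPM (-0.97 ± 0.35, adjusted p = 0.519) and Acp36DE from 14403 ± 243 to 8837 ± 908 CPM (-0.70 ± 0.42, adjusted p = 0.821), without overlap between the ages and without passing.

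Here 13 genes changed (edgeR), 4 up and 9 down, 62 with the replicate block and 371 (90 up, 281 down) without monogamous population 1, which enters through the shared dispersion. Size factors from testis genes gave 2 up and 2 down, a filter at a mean of 5 CPM gave 5 calls, and leaving out any 1 of the 6 polygamous libraries gave 2 to 6. DESeq2 gave 129 calls, the legacy quasi-likelihood fit 8 and a fit of only the 6 libraries compared 482. Of 77 named seminal fluid proteins 2 fell (5 with the replicate block, 10 adjusted over the list alone) and 72 had a negative change; the median was -0.45 (adjusted p = 8.27e-31, and adjusted p = 0.403 with an estimated correlation). COPI, COPII and Golgi traffic had a median of -0.29 (adjusted p = 9.33e-17, and adjusted p = 0.403 with an estimated correlation) and ER translocation and folding -0.21 (adjusted p = 8.68e-09, and adjusted p = 0.478 with an estimated correlation), each with 0 members past the threshold over all genes (1 gene of the traffic list with the replicate block). Ribosomal proteins had a median of 0.01 and were not called (adjusted p = 0.607). The spermatid and the Y-linked lists, at adjusted p = 0.0475 each, were lost with the replicate block (0.112 and 0.184) and with an estimated correlation (adjusted p = 0.762 and 0.587 without the block).

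Of the 72 genes called in monogamous and the 13 called in polygamous males, 9 were shared, all in the same direction, against 0.0711 expected for independent lists. The 2 comparisons used different libraries but shared 1 dispersion estimate per gene. Their calls were therefore not independent, and the expected numbers in this paragraph are a rough guide. All 72 and all 13 genes had the same sign in the other regime. Without population 1, 70 genes were shared of 91 and 371 (2.55 expected), and 91 and 367 had the same sign. With the replicate block 43 were shared of 252 and 62 (1.19 expected), and 233 and 60 had the same sign.

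The difference between the regimes in their age change was the design's direct test of whether maturation altered under sexual selection. Among those with a mean of at least 5 CPM, the genes with the smallest p were glob1, which fell less in polygamous males (difference 0.78 ± 0.18 on the log2 scale), CG5326 (-1.46 ± 0.34), which stood at 8.58 ± 1.89 and 18.2 ± 5.42 CPM in monogamous males at 48 and 96 h and at 15.9 ± 3.19 and 12.3 ± 1.31 CPM in polygamous males, and the serpin Spn55B (-0.64 ± 0.16). None of them passed (edgeR adjusted p = 0.919 each), nor did CG15784 (-0.93 ± 0.26), lncRNA:CR45883 (-0.83 ± 0.22), the RNA helicase gene Ddx56 (-0.48 ± 0.13), CG10553 (0.57 ± 0.17), CG10486 (0.44 ± 0.15), lncRNA:CR43846 (0.41 ± 0.13) and CG14506 (0.30 ± 0.10). In all, 0 genes passed by edgeR, 325 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. With the replicate block 1 gene passed, Sfp24Ba (-8.29 ± 0.71, adjusted p = 0.0230, chosen after its value was seen), at 15.9 and 13.6 CPM in the 96 h libraries of monogamous populations 1 and 3 and at most 0.368 CPM in the 10 others.

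By list, named seminal fluid proteins had a median difference of -0.56 (72 of 77 negative, adjusted p = 2.43e-23, and adjusted p = 0.479 with an estimated correlation), candidates -0.59, secondary cell markers -0.69 and ribosomal proteins -0.15, each with 0 members past the threshold. Without population 1 the medians were -0.27 for candidates, -0.32 for secondary cell markers and -0.15 for ribosomal proteins. The named list's median was then -0.29, with 73 of 77 negative (adjusted p = 3.63e-29, and adjusted p = 0.475 with an estimated correlation). That fit with the replicate block called 87 genes, of them 23 of the 77 named seminal fluid proteins, 15 of 61 candidates, 6 of 9 genes of the sex peptide network and 4 of 9 secondary cell markers. Examples chosen after their values were seen were lectin-46Ca (-0.35 ± 0.05), lectin-46Cb (-0.41 ± 0.05), Acp32CD (-0.33 ± 0.05) and Acp53C14b (-0.36 ± 0.05), all with a lower age change in polygamous males, set against 2 monogamous populations. The duct and bulb list (adjusted p = 0.0287), the spermatocyte list (0.0469) and the haemocyte list (0.0480) passed only with the replicate block over all libraries and the unfolded protein response (0.0608) only without it, and the estimated correlation gave adjusted p of 0.630 or more with the block.

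At 48 h, the genes with the smallest p between polygamous and monogamous males, among those with a mean of at least 5 CPM, were 2 long non-coding RNAs. lncRNA:CR43713 (2L, 5431842 to 5432604) was at 10.7 ± 2.94 CPM under polygamy and 1.55 ± 0.498 CPM under monogamy (6.77-fold, 2.76 ± 0.34, edgeR adjusted p = 0.0705). lncRNA:CR44612 (2L, 7142304 to 7145263), which overlaps Pvf3 on the other strand, was at 13.4 ± 6.29 against 0.328 ± 0.310 CPM (40.4-fold, 5.34 ± 0.74, adjusted p = 0.0892). CG7091 (2.11-fold), Spn55B (1.55-fold) and the translation initiation factor gene eIF3g1 (1.29-fold) were also higher, and CG3502 (4.56-fold), lncRNA:CR44131 (1.34-fold), CG42764 (1.29-fold), CG42571 (1.28-fold) and the globin gene glob3 (1.28-fold) lower under polygamy. None of these 10 genes passed, and their groups did not overlap.

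At this age 0 genes passed by edgeR, 2249 had an unadjusted p under 0.05, DESeq2 called 137 and limma-voom 0. The groups did not overlap in 22.3% of genes, against 10% by chance. Ribosomal proteins had a positive median of 0.20 (43 up and 2 down adjusted over the list alone, camera adjusted p = 1.31e-19, and adjusted p = 0.450 with an estimated correlation). They took 1.69% ± 0.0761 of counts under polygamy against 1.47% ± 0.0158 under monogamy (exact permutation p = 0.1, the smallest possible). Named seminal fluid proteins (0.49), secondary cell markers (0.69), ER translocation and folding (0.34) and COPI, COPII and Golgi traffic (0.28) had positive medians and were called with the preset correlation (adjusted p = 0.450 each with an estimated correlation). The divergent library of population 1 lay on the monogamous side. Without population 1 these medians were 0.20, 0.25, 0.10 and 0.12, and those of ribosomal proteins 0.21 and of muscle 0.19. Oxidative phosphorylation had a median of -0.05, which turned to 0.05 without population 1. With size factors from testis genes it turned to 0.10, below the median of all genes in that fit (0.14). The median for muscle was 0.28 and its mean -0.0056 (adjusted p = 9.65e-05, and adjusted p = 0.450 with an estimated correlation). No panel gene passed: SP gave 0.35 ± 0.23, Acp26Aa 0.62 ± 0.35 and lectin-46Ca 0.93 ± 0.55.

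At 96 h, lncRNA:CR44612 was again higher under polygamy, at 12.98 ± 5.17 against 0.498 ± 0.476 CPM (4.70 ± 0.66, edgeR adjusted p = 0.160). HP6, a heterochromatin protein gene that overlaps dpy on the same strand, was at 15.2 ± 1.46 against 10.05 ± 1.43 CPM (1.52-fold), glob1 was 1.46-fold, HP4 1.31-fold and mRpL27, a mitochondrial ribosomal protein gene, 1.29-fold higher. CG31157 was 2.66-fold, CG5397 1.46-fold and kl-3, a Y-linked dynein gene, 1.22-fold lower under polygamy. Obp56g (38.4-fold) and Sfp24Bb (109-fold) were lower as fitted, because 2 of 3 monogamous libraries held them at 53.2 and 72.9 CPM and at 32.6 and 38.0 CPM, while monogamous population 2 held 0.892 and 0.0510 CPM. None of the 10 passed.

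At this age 0 genes passed by edgeR, 486 had an unadjusted p under 0.05, DESeq2 called 23 and limma-voom 0. The DESeq2 calls included Ebp, EbpII, Sfp87B and Sfp60F, chosen after their values were seen, and Obp56g and Sfp24Bb. These stood high only in the 96 h libraries of monogamous populations 1 and 3. Without the 96 h library of monogamous population 2, edgeR called 25 genes, and without that of population 3 it called 3. The first of these fits left only those of populations 1 and 3 for monogamy at 96 h. The groups did not overlap in 10.8% of genes, against 10% by chance. Gut enzymes had a median of -3.75 (0 of 15 passing, adjusted p = 1.87e-09, and adjusted p = 0.999 with an estimated correlation), with 0.0177% of counts in the 96 h library of monogamous population 1 and at most 0.00373% in the other 96 h libraries. The duct and bulb list had a median of -0.12 (adjusted p = 0.0319, and adjusted p = 0.999 with an estimated correlation; 2 down adjusted over the list alone) and named seminal fluid proteins -0.04 (adjusted p = 0.219; 6 down adjusted over the list alone). Without the 96 h libraries of monogamous populations 1 and 3 these medians were 0.20 and 0.14, values that rest on population 2 as the only monogamous library at 96 h. Without population 1 gut enzymes were not called (-0.90, adjusted p = 0.0965). Named seminal fluid proteins were then called (-0.09, adjusted p = 0.000776, and adjusted p = 0.775 with an estimated correlation). Mitochondrial genome transcripts had a median of -0.11 and a mean of 0.09 (adjusted p = 0.0445, and adjusted p = 0.999 with an estimated correlation).

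**Figure D4:**
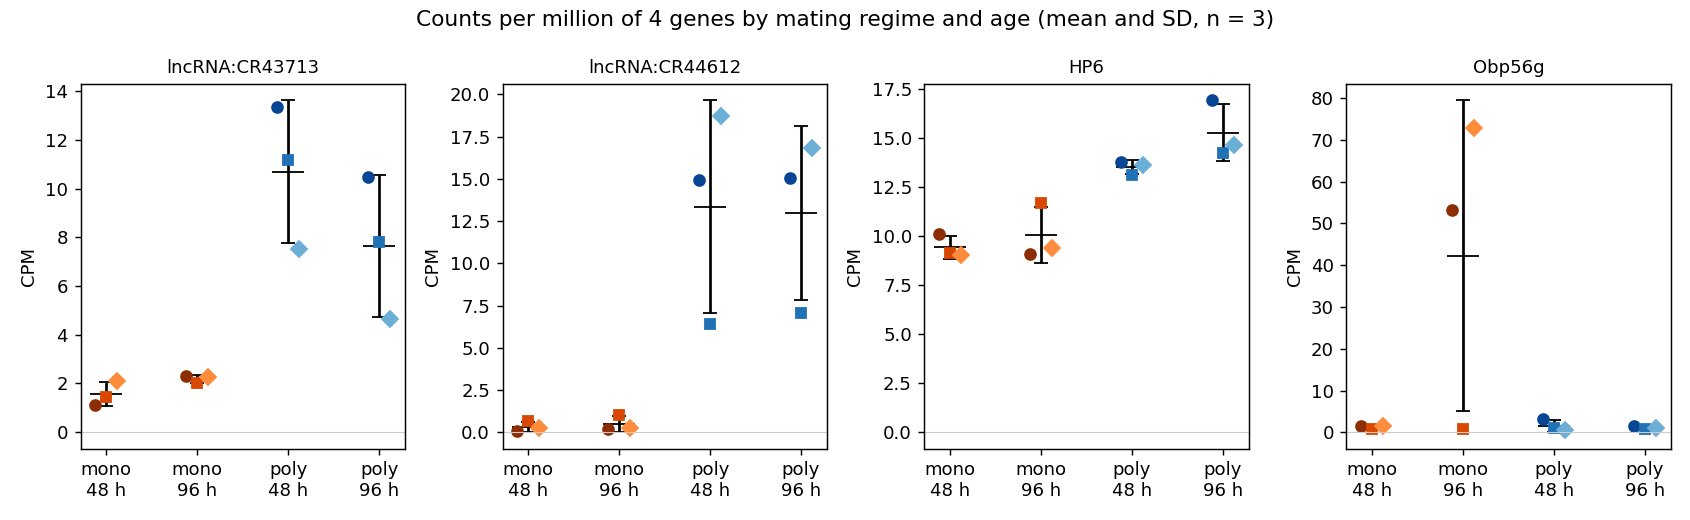
CPM of 4 genes (vertical axis) in the 4 groups of regime and age (horizontal axis); points are libraries, with markers set by population, and horizontal and vertical lines are the mean and SD (n = 3). lncRNA:CR44612 stood at 13.4 ± 6.29 CPM in polygamous and 0.328 ± 0.310 CPM in monogamous males at 48 h, and Obp56g stood at 53.2 and 72.9 CPM in only 2 monogamous libraries at 96 h.

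Summed over ages, the regimes were compared as 3 populations against 3. lncRNA:CR43713 was at 9.07 ± 2.88 CPM under polygamy and 1.91 ± 0.238 CPM under monogamy (4.74-fold, 2.24 ± 0.28), and lncRNA:CR44612 at 13.2 ± 5.73 and 0.425 ± 0.404 CPM (31.3-fold, 4.97 ± 0.64). The cytochrome P450 gene Cyp4p2 was 1.81-fold, the lipid phosphatase gene FIG4 1.60-fold and HP6 1.48-fold higher, and CG9747 2.71-fold, CG5397 1.40-fold, lncRNA:CR9284 1.18-fold, CG2955 1.18-fold and CG31910 1.16-fold lower under polygamy. None passed (edgeR adjusted p = 0.520 each). In this comparison 0 genes passed by edgeR, 1280 had an unadjusted p under 0.05, DESeq2 called 74 and limma-voom 0, and edgeR called 9 without monogamous population 2 and 2 without polygamous population 3. The groups did not overlap in 18.3% of genes, against 10% by chance. Ribosomal proteins had a median of 0.11 (adjusted p = 4.38e-13, and adjusted p = 0.481 with an estimated correlation), COPI, COPII and Golgi traffic 0.17 (adjusted p = 0.481 with an estimated correlation), and named seminal fluid proteins a median of 0.23 against a mean of -0.17 (adjusted p = 0.489 with an estimated correlation), each with 0 members past the threshold. Leaving out population 1 gave medians of 0.12 for ribosomal proteins, 0.08 for COPI, COPII and Golgi traffic and 0.05 for named seminal fluid proteins. For muscle the median was 0.16 and the mean -0.05 (adjusted p = 9.44e-06, and adjusted p = 0.481 with an estimated correlation).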

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

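The tests of explanations in this part were chosen after the results were seen, except the test of library scaling. Of 78 values compared within an age, shares of counts by list and CPM of panel genes, 22 had 1 library set apart from the other 5 (Dixon's gap ratio), 19 of them in the 48 h library of monogamous population 1. By chance about 1 in 20 values, here 3.9, would have 1.

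In that library named seminal fluid proteins took 3.07% of counts (6.09% to 7.73% in the others at 48 h), candidates 1.40% (3.32% to 4.38%), secondary cell markers 0.0313% (0.173% to 0.249%), ER translocation and folding 0.379% (0.648% to 0.741%) and COPI, COPII and Golgi traffic 0.262% (0.350% to 0.399%). Also lower were muscle at 0.282% (0.323% to 0.348%), Malpighian tubule at 0.0186% (0.0273% to 0.0312%) and detoxification at 0.275% (0.345% to 0.377%). Higher were the spermatocyte programme at 0.581% (0.461% to 0.506%), spermatids at 6.04% (4.58% to 5.09%), fat body at 0.0382% (0.0145% to 0.0213%), haemocytes at 0.0539% (0.0349% to 0.0412%), immune effectors at 0.0223% (0.00789% to 0.0119%) and oxidative phosphorylation at 0.826% (0.658% to 0.693%). Among panel genes Acp26Aa stood at 793 CPM (2351 to 3249 in the others), Acp36DE at 2772, Dup99B at 2374, betaTub85D at 3429 (2524 to 2734) and Mst87F at 1475 CPM (872 to 979).

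An even shortage of gland tissue was argued against as the whole cause of the low seminal fluid transcripts in this pool. It would lower gland transcripts alike. The log2 ratios of named seminal fluid genes to the other 48 h libraries instead had an interquartile range of 0.852 around a median of -1.38. In any other 48 h library that range was at most 0.245. No library with a known shortage was there for comparison, and 3 genes of the list were also duct and bulb genes. A shortage therefore stays open as a part of the cause. Swapped ages within population 1 were argued against by the age score of its 96 h library, -0.113, near the other 96 h libraries (-0.132 to -0.0577) and far from the other 48 h libraries (-0.884 to -0.796), with its 48 h library at -0.361. An earlier point on the same course would raise the 386 genes that fell with age elsewhere. Their median log2 ratio was -0.683 (interquartile range -1.11 to -0.0814). That value cannot decide, since these genes include seminal fluid and secretion genes, whose low level is the pattern in question. No library was younger than 48 h either, so an earlier point stays open. A loss of part of the gland or of its secondary cells, a wrong label from outside the 2 libraries and a difference of this population also stay open, untested, in 1 pool.

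Transcripts of the ejaculatory bulb stood high in 2 monogamous libraries at 96 h, those of populations 1 and 3: Ebp at 506 and 487 CPM (at most 8.53 in the other 10 libraries), Sfp87B at 155 and 166, EbpII at 141 and 136 and Sfp60F at 95.9 and 103 CPM. Over the 11 genes with this pattern the SD of the log2 ratios between the 2 libraries was 0.233, and population 2 had a median log2 ratio of -0.364 to the polygamous libraries. These genes were chosen for standing high in the 2 libraries and low in the other 10, population 2 among them, so neither value decides. Bulb tissue in both pools, an effect of monogamy and a difference of populations 1 and 3 in bulb expression all stay open.

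Outside population 1, named seminal fluid transcripts had a negative median change, with 26 of 77 genes past the threshold and the list lost at adjusted p = 0.201 with an estimated correlation. A smaller share of gland RNA would lower the secondary cell markers too, and their median log2 change was 0.0336, above the interquartile range of the named list (-0.554 to -0.0783, median -0.272). By regime it was 0.20 in monogamous males (named list up to 0.03 at the upper quartile) and -0.08 in polygamous males (-0.32), where 7 of 9 markers were negative, so a smaller share was argued against as the whole cause and stays open as a part in polygamous males. Scaling of the libraries was argued against by size factors from testis genes, with which the median was -0.256 (interquartile range -0.534 to -0.0612) and 62 of the 77 changes were negative. A lower output of main cells with age stays as a hypothesis, found and tested on the same data, and a lower share of main cells within the gland was not tested.

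Of the 30 lists, 13 differed between the regimes in their age change by camera with the preset correlation, polygamous minus monogamous on the log2 scale. The medians were -0.56 for named and -0.59 for candidate seminal fluid proteins, -0.67 for the sex peptide network, -0.69 for secondary cell markers, -0.30 for ER translocation and folding, -0.23 for COPI, COPII and Golgi traffic, -0.0602 for the unfolded protein response, -0.15 for ribosomal proteins, -0.15 for insulin and TOR signalling and -2.83 for gut enzymes. Muscle had a median of -0.19 and a mean of 0.16, spermatids a median of 0.12 and oxidative phosphorylation one of 0.0847. None held with an estimated correlation (adjusted p = 0.479, with 0.552 for spermatids and 0.692 for oxidative phosphorylation), and 0 members of these lists passed (edgeR). Without population 1, whose 48 h library was set apart, the medians were -0.29 for named and -0.27 for candidate seminal fluid proteins, -0.32 for the sex peptide network, -0.32 for secondary cell markers, -0.04 for ER translocation and folding, -0.08 for COPI, COPII and Golgi traffic and -0.15 for ribosomal proteins. In that fit the calls of the unfolded protein response (-0.04), insulin and TOR signalling (-0.03), gut enzymes (-0.58), muscle (-0.05), spermatids (0.02) and oxidative phosphorylation, which turned to -0.0365, were lost.

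Gut enzymes took 0.0177% of counts in the 96 h library of monogamous population 1 and 0.00151% to 0.00373% in the other 96 h libraries. Ribosomal proteins took 1.58% in that of monogamous population 2 (1.76% to 1.83% in the others). Mitochondrial genome transcripts took 2.13% in that of monogamous population 3 (1.71% to 1.82% in the others).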

How the results depend on the processing

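The alternatives without population 1, with and without the block, without the 2 libraries with bulb transcripts and with the legacy quasi-likelihood fit were chosen after the results were seen, and the others before. A gene result counted as reversed where its sign turned and it was called in either fit. For lists the direction given by the list test had to turn, which can differ from the sign of the median. Values near 0 that passed in neither fit, such as that of Abd-B between regimes at 48 h (0.07, and -0.14 without population 1), counted as the same. Outside left-out libraries, 2046 gene results were the same, 48 stronger, 149 weaker and 0 reversed, and of list results 1031 were the same, 3 stronger, 289 weaker and 15 reversed. With 1 library left out, or 1 population for population sums, 1136 gene results were the same, 10 stronger, 264 weaker and 0 reversed. Of list results 688 were then the same, 5 stronger, 89 weaker and 10 reversed. Genes that a filter removed have no value there. The cause was not tested for any difference in this part unless given. Depth limited little, since 3 counts were worth at most 0.0956 CPM. Of simulated 1.5-fold changes 34.3% were recovered in monogamous males and 52.2% averaged over regimes.

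Against 72 calls for age in monogamous males, 13 in polygamous males and 194 averaged, and 0 in the regime comparisons, DESeq2 gave 338, 129 and 627 calls for age, 137 between regimes at 48 h, 23 at 96 h and 74 over population sums. Size factors from testis genes gave 27 and 4 calls within the regimes. limma-voom gave 45 in monogamous males, a filter at a mean of 5 CPM gave 5 and the legacy quasi-likelihood fit gave 8 in polygamous males. Fits of only the 6 libraries compared gave 3 calls in monogamous and 482 in polygamous males, with fewer libraries for the dispersion.

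With the replicate block, which paired the 2 libraries of a population, there were 252, 62 and 475 calls for age and 1 for the difference of age changes, and it changed no other call of a named gene or list than those given beside the results. Numbers across regimes did not pair the libraries: same-numbered libraries correlated at 0.0094, 0.045 and 0.096 at 48 h and at -0.15, 0.20 and -0.064 at 96 h. A block of these numbers gave 9 calls between regimes at 48 h and called 5 lists at 96 h, against 9 lists without it.

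Without monogamous population 1, 371 genes changed in polygamous males and 805 on average. With the replicate block added there were 1029 calls in monogamous males, 1973 in polygamous males, 2874 on average and 87 for the difference of age changes. Without population 1 camera called 14 lists between regimes at 96 h, and 0 list shares passed averaged over regimes, where 4 lists were at the smallest p that 5 libraries against 5 can give (adjusted p = 0.0595). Without the 2 libraries with bulb transcripts, fewer libraries gave 5, 2 and 24 calls for age and 1 between regimes at 96 h.

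Camera with an estimated correlation called 0 lists in each of the 7 comparisons and fry called 0 in each except the averaged age change, with 1, against 16, 16, 15, 15, 9, 13 and 15 with the preset correlation.

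List results that turned were these, by their median unless the direction of camera is named. In monogamous males with age, named seminal fluid proteins went from 0.096 to -0.139 without population 1, -0.141 with the replicate block added and -0.137 without the 2 libraries with bulb transcripts, and candidates to -0.0162 without population 1 and -0.0164 with the block added. For gut enzymes, with a median of 0.858 without population 1 and with the block, the direction of camera turned. Averaged over regimes, the direction of camera turned for candidates. Their median was near 0 and negative over all libraries, and went to -0.166 without population 1 and -0.167 with the block. Between regimes at 48 h, oxidative phosphorylation went to 0.0487 without population 1. With size factors from testis genes it went to 0.0985, below the median of all genes in that fit (0.139). For the difference of age changes it went to -0.0365 without population 1 and -0.0358 with the block. Without the 2 libraries with bulb transcripts, named seminal fluid proteins (0.138) and duct and bulb (0.196) turned between regimes at 96 h. For the mitochondrial genome only the direction of camera turned there, and its median stayed negative (-0.0251). In that fit 1 library stood for monogamy and was assumed to vary like the other groups.

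With 1 library left out, calls for age ranged from 5 to 157 in monogamous males, 2 to 6 in polygamous males and 80 to 914 on average. Calls ranged from 0 to 0 between regimes at 48 h, 0 to 25 at 96 h and 0 to 1 for the difference of age changes. Over population sums, where both libraries of 1 population were left out, calls ranged from 0 to 9. Medians in monogamous males ranged from -0.185 to 0.390 for named seminal fluid proteins, -0.0263 to 0.514 for candidates and 0.00688 to 2.18 for gut enzymes, and averaged over regimes from -0.167 to 0.158 for candidates. Between regimes they ranged from -0.124 to 0.0490 for oxidative phosphorylation at 48 h, -0.0305 to 0.0742 for ribosomal proteins and -0.166 to -0.0324 for the mitochondrial genome at 96 h, -0.170 to -0.0483 for the mitochondrial genome over population sums and -0.0351 to 0.153 for oxidative phosphorylation in the difference of age changes.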

Other observations

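All genes in this part were chosen after their values were seen, from the fit without monogamous population 1 unless another is named, and the counts of splits were also chosen then. Outside the lists and averaged over regimes, the genes given here changed between 48 and 96 h. Orct, an organic cation transporter gene, fell 2.05-fold (-1.04 ± 0.05 on the log2 scale, SE, 5 populations), CG34447 1.98-fold (-0.99 ± 0.07), ics 1.79-fold (-0.84 ± 0.06), Strn-Mlck, a myosin kinase gene, 1.71-fold (-0.78 ± 0.05), CG11034 1.66-fold (-0.73 ± 0.05) and wb, a laminin gene, 1.53-fold (-0.61 ± 0.05). LUBEL, a ubiquitin ligase gene, fell 2.26-fold (-1.18 ± 0.10), CG5078 2.04-fold (-1.03 ± 0.09) and Mdh2, a malate dehydrogenase gene, 1.37-fold (-0.45 ± 0.05). The Golgi gene Grasp65 fell 1.30-fold (-0.38 ± 0.05), Tpst, a tyrosine sulfotransferase gene, 1.27-fold (-0.35 ± 0.04) and Pgant5, which starts O-glycans, 1.26-fold (-0.33 ± 0.04). In population 1, Orct, CG34447, Strn-Mlck, CG11034, wb, LUBEL, CG5078, Grasp65, Tpst and Pgant5 rose instead. Their log2 changes there were 0.24 (wb) to 0.93 (CG11034), while ics and Mdh2 fell there too. PPO2, a prophenoloxidase gene of crystal cells, rose 4.21-fold (2.07 ± 0.19), while in population 1 it fell (-0.59). CG13255 rose 1.73-fold (0.79 ± 0.05), CG3640 1.62-fold (0.70 ± 0.06), the DNA repair gene FANCI 1.43-fold (0.52 ± 0.06), the histone gene His4r 1.40-fold (0.49 ± 0.06), the cathepsin gene CtsF 1.32-fold (0.40 ± 0.05) and the histone chaperone gene Nap1 1.28-fold (0.36 ± 0.04). Each had an edgeR adjusted p from 2.78e-05 (Orct) to 0.00277 (Pgant5).

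Within the lists, the same fit had Est-6, a seminal fluid esterase gene, 1.95-fold lower at 96 h (-0.96 ± 0.20, adjusted p = 0.0339), the serpins Spn77Bb 2.04-fold (-1.03 ± 0.15) and Spn53F 1.63-fold lower (-0.70 ± 0.07) and the bomanin BomS3 5.29-fold lower (-2.40 ± 0.29), while RpL22 rose 1.25-fold (0.33 ± 0.06) and CycB, a mitotic cyclin gene, 1.15-fold (0.21 ± 0.04). With the replicate block in that fit, the age change differed between regimes for CG6770 (-0.53 ± 0.05, adjusted p = 0.00119), the homeobox gene dve (-0.70 ± 0.11), Mst57Da (-0.37 ± 0.06), Acp63F (-0.38 ± 0.06), Sfp77F (-0.40 ± 0.06), Acp53Ea (-0.38 ± 0.06) and the sex peptide network protease CG9997 (-0.33 ± 0.05), all lower in polygamous males.

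In the 48 h library of monogamous population 1, lectin-46Ca was 9.52-fold lower than the mean of the other 48 h libraries, CG9029 stood at 148 CPM (884 to 1179 in the others), CG17575 at 59.0 CPM (301 to 504) and Spn28F at 442 CPM (2105 to 2692). The stress gene TotA was 9.40-fold higher, Obp99c stood at 77.9 CPM (7.28 to 15.8), CG4716 at 88.7 CPM (10.99 to 14.6), Lsd-1, a lipid droplet gene, at 20.8 CPM (3.23 to 6.23) and NimC1, a haemocyte receptor gene, at 16.1 CPM (3.61 to 5.47).

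Averaged over regimes, 1 of the 100 splits of the 12 libraries drawn, the real one, gave 194 genes and the highest of the others gave 0. Of the 100, 32 parted the 2 libraries of every population as the real one did, and only these respect the block. Among the 32 the real split alone reached its count, at the smallest share they can give. This argues against chance without excluding it. The highest of the remaining 68 was also 0. The other comparisons allow 10 splits each, too few for a share under 0.05. In monogamous males the real split gave 72 genes and the highest other 2, and in polygamous males 13 and 0, so 1 split reached the count in each. Between regimes at 48 h, at 96 h and for the difference of age changes the real split and the highest other gave 0 genes, and over population sums 0 and 4, so all 10 splits reached the count (edgeR). Genes with an unadjusted p under 0.05 numbered 2249 in the real split at 48 h and 1380 in the highest other, 486 and 475 at 96 h, 325 and 190 for the difference of age changes and 1280 and 881 over population sums.

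The share of counts did not overlap between the regimes in 12 of the 30 lists at 48 h, 4 at 96 h and 9 over population sums, and between the ages in 8 lists in monogamous and 14 in polygamous males, against 10% by chance.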
